A study of Mus musculus with 15 samples.

How the data were processed

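Gene expression was measured in triceps muscle of mice that lack their own Gne gene and carry a transgene for a mutant form of GNE, a model of GNE myopathy. Per the labels' protocols, total RNA was extracted from cryostat sections of frozen muscle, copied to cDNA from oligo-dT primers and transcribed into biotin-labelled cRNA, so each array carried 1 colour. Of the 15 arrays, 9 came from mice without treatment and 6 from mice given N-acetylcysteine (NAC) at 0.1% in the drinking water. The labels give a separate mouse number for each sample, and p-values here measure the spread between these samples. The mouse numbers of the treated animals all follow those of the untreated ones, and no litter, sex, age or array date is given in the sources used here. No wild-type array was among the samples analysed here.

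The deposited values are linear intensities that the authors had already normalized. The normalization method, the array design, the scanner and the background correction are not given in the sources used here. The values themselves show the outcome of the normalization: when the 36227 values of each array were sorted, values of the same rank differed across the 15 arrays by at most 0.0383 on the log2(value + 16) scale, and by 0.000146 in the median. Every array therefore had a median intensity of 18.28, and a change that moved all transcripts together would no longer show in these values. The lowest value, 0.001, was shared by 246 to 401 features on each array and is called the floor value here. Whether it stands for intensities at or below background or for spots left unread is not given in the sources used here. No array was identical to another.

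Features are numbered from 1 to 36227 in the deposited table, and the files do not pair these numbers with genes. No gene could be named, Gne included, and the gene lists and cell type markers chosen before the data were examined were not tested. Control features could not be set apart by name either, so all 36227 features entered each test. The table held 0 columns besides the feature number and the 15 arrays.

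The grouping, the tests, the thresholds and most alternatives were chosen before the data were examined. Intensities were put on the scale log2(value + 16). A fold change on this scale understates the change of dim features, since the median intensity was close to the added constant. NAC arrays were compared with untreated arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a trend in the variance prior, as a moderated two-sided test per feature. P-values were adjusted by the Benjamini-Hochberg method over the 36227 features, and the threshold was an adjusted p under 0.05. The same tool was used for a slope per labelled week of treatment over the 6 NAC arrays. The spread between mice was compared as the ratio of the median within-group SD, with a two-sided permutation test over all 5005 splits of the arrays after removal of each group's mean. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

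The rule for single features asked for the 10 largest rises and the 10 largest falls past the threshold. As features have no gene names here, it was shortened to the largest rise and the largest fall. Both turned out to hold the floor value in 1 group, so the largest rise and the largest fall among features with no floor value on any array were added after the values had been seen. Where all arrays of 1 group hold the floor value, the test compares measured levels with a constant, so no p-value or fold change is given for such a feature.

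The fit was tested on simulated data with the measured mean and spread of each of the 36227 features, in which 200 features were changed. For NAC against untreated, 8.96% of the changes of 0.25 on the log2 scale were recovered, 70.1% of those of 0.5 and 98.5% of those of 1, with 6 false calls. For the slope within the NAC group, 0% of the changes of 0.1 per week were recovered, 25.4% of those of 0.2 and 90.9% of those of 0.4, with 5 false calls. Recovery depends on how many features change, since the Benjamini-Hochberg adjustment is stricter when fewer do. The number of arrays limits the precision.

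Alternatives set before the data were examined were quantile normalization, centring each array on its median, the 50% of features with the higher mean level, an added constant of 1, intensities under 32 set to 32, array weights, a robust variance prior, a variance prior without trend, an adjusted p under 0.10, an unmoderated test per feature with unequal variances, and leaving out each array in turn. Added after seeing the data were floor values set to missing, removal of all features with a floor value (also for the correlations and principal components of the arrays), removal of each array's trend along the feature number (a running median over 201 features), and removal of 1 untreated array together with the floor features.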

Results

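The series was set up to look for the mechanism of GNE myopathy and for pathways that respond to N-acetylcysteine. GNE is the enzyme that starts the synthesis of sialic acid, and GNE myopathy is an inherited muscle disease caused by mutations in it. N-acetylcysteine is an antioxidant and a precursor of the cysteine in glutathione. Triceps muscle of 9 untreated and 6 NAC-treated mice of the same mutant genotype was profiled on 1-colour arrays with 36227 features. Labelled durations of treatment ran from 30 to 35 weeks, with 1 mouse at each. The median normalized intensity was 18.28 on every array and the highest was 21541. Between 246 and 401 features per untreated array and between 293 and 344 per NAC array were listed at the floor value of 0.001. The largest share on any array was 1.11% of features.

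Arrays of the same group resembled each other more than arrays of different groups, in large part through features with a floor value. Across features, Pearson's r of log2 intensities averaged 0.9799 over the 36 pairs of untreated arrays, with a range from 0.9681 to 0.9854. It averaged 0.9801 over the 15 pairs of NAC arrays, with a range from 0.9741 to 0.9858. Over the 54 pairs of an untreated with a NAC array it averaged 0.9661, from 0.9473 to 0.9737. Features are not independent replicates, so these values describe the arrays only. The first principal component held 32.3% of the variance and separated the groups, with untreated arrays between -33.6 and -14.5 and NAC arrays between 26.0 and 34.5. The second held 10.4%. Without the features that hold a floor value on any array, an alternative added after seeing the data, the mean r between groups rose to 0.9768, against 0.9807 within untreated and 0.9814 within NAC arrays. The first component then held 20.4% of the variance, with untreated arrays between -40.5 and 1.25 and NAC arrays between 10.1 and 28.1, and the distance between the group means fell from 51 to 29.3.

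**Figure D1:**
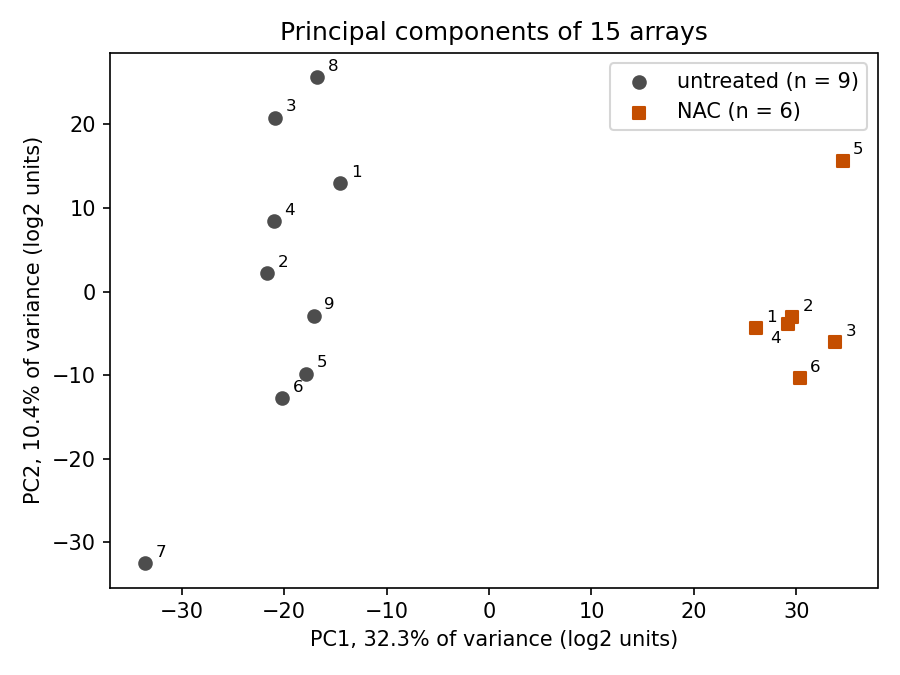
Scores of the 15 arrays on the first (x axis, 32.3% of variance) and second (y axis, 10.4% of variance) principal components of log2(intensity + 16), in log2 units, with 1 point per mouse and the replicate number beside it. The 9 untreated arrays lie between -33.6 and -14.5 on the first component and the 6 NAC arrays between 26.0 and 34.5, while the groups overlap on the second. All features enter the plot, and without those with a floor value the groups lie closer, up to 1.25 for untreated and from 10.1 for NAC arrays.

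The main comparison asked which transcripts differed between treated and untreated muscle. At an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1908 features (5.27%) differed, of which 1123 were higher and 785 lower in NAC muscle. These counts include 247 features at the floor on every array of 1 group only, tested against a constant. Features with no floor value on any array made up 1641 of the 1908. An unadjusted p under 0.05 was reached by 6648 features. Most changes were small. The median size among the 1908 was 0.404 on the log2 scale, 591 changed by over 0.5 and 171 by over 1. Among those with no floor value on any array, 389 changed by over 0.5 and 26 by over 1. On 757 features the 6 NAC arrays lay entirely above (440) or entirely below (317) the 9 untreated arrays, where chance gives 0.04% of features, or 14.5. This number was 507 without features with a floor value and 497 with intensities under 32 set to 32. The number of features past the threshold fell to 959 with intensities under 32 set to 32 and to 1252 without NAC replicate 3, and it rose to 3024 at an adjusted p under 0.10. The number lower in NAC muscle fell from 785 to 320 with intensities under 32 set to 32, to 509 without NAC replicate 2, to 485 without NAC replicate 3 and to 513 without NAC replicate 5. The labels name no array batch. The 247 floor features part the arrays exactly by group and are hard to ascribe to silent transcripts, as given in the last part. A technical difference between the groups is thus a candidate, and treatment cannot be told apart from a batch that ran with it.

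The floor value followed the groups. Of the 36227 features, 127 were at the floor on all 9 untreated arrays and on no NAC array, and 120 were at the floor on all 6 NAC arrays and on no untreated array. All of these 247 features were past the threshold, in a test that sets measured levels against a constant, and 142 of the 171 features with a difference of over 1 on the log2(value + 16) scale were among them. The remaining 2399 features with a floor value on at least 1 array gave 20 calls. Intermediate cases were rare. Among untreated arrays, 1346 features were at the floor on 1 array, 84 on 2 arrays, 4 on 3, 1 on 5, 1 on 7, 5 on 8 and 134 on all 9. Among NAC arrays, the numbers were 1035 on 1 array, 60 on 2, 1 each on 3, 4 and 5, and 123 on all 6. With the level of a feature taken as its median intensity over the arrays of the group that read it, not its mean, the features read only on untreated arrays had levels from 2.37 to 4308, with a median of 19.6. Those read only on NAC arrays had levels from 3.62 to 1900, with a median of 20.9. The size of these differences depends on the floor value and on the added constant. It served only to count and rank them and is not given as a fold change.

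**Figure D2:**
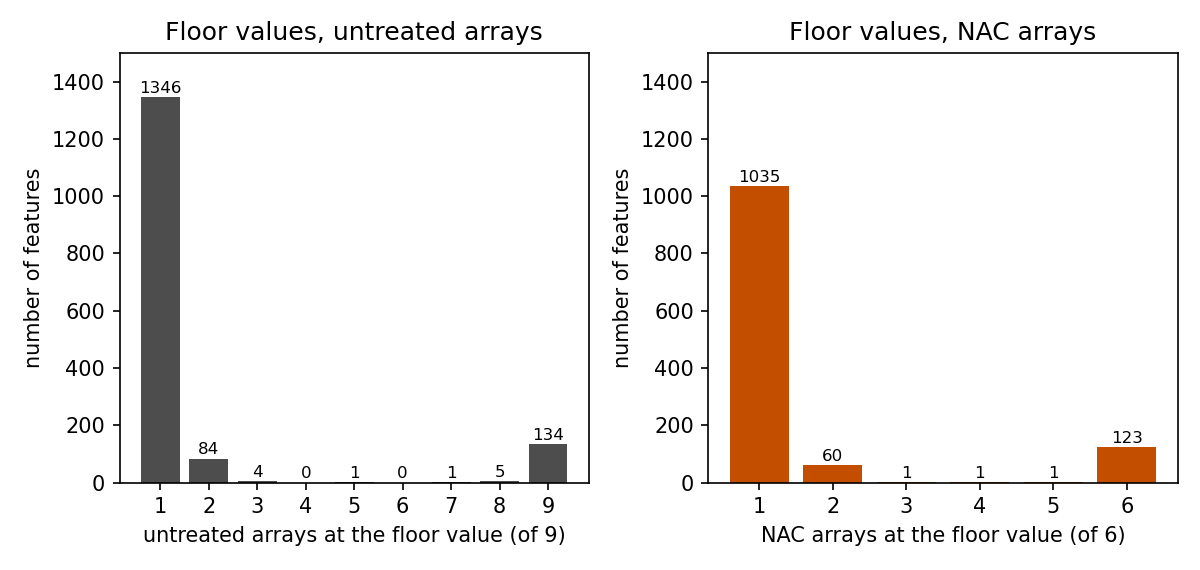
Number of features (y axis) by how many untreated arrays (left, of 9) or NAC arrays (right, of 6) list them at the floor value (x axis). Most features with a floor value have it on 1 array, 134 have it on all 9 untreated arrays and 123 on all 6 NAC arrays, and few lie between.

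**Figure D3:**
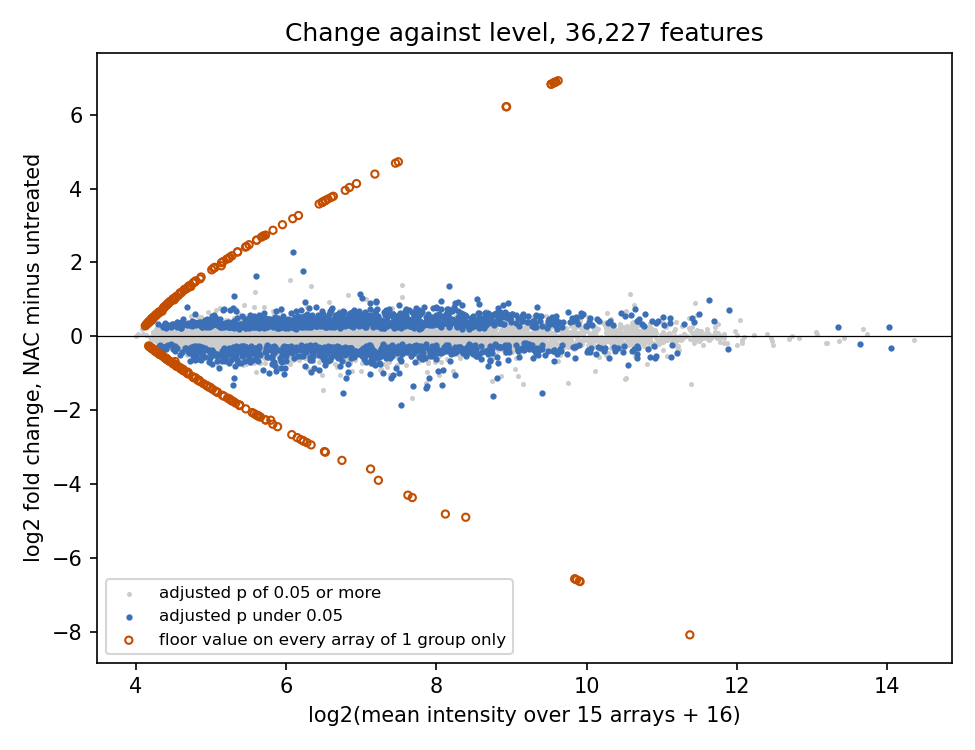
Log2 fold change, NAC minus untreated (y axis), against log2(mean intensity over 15 arrays + 16) (x axis) for 36227 features, with features at an adjusted p under 0.05 in blue and the 247 with the floor value on every array of 1 group only as open circles. The open circles lie on 2 arms set by their level and the floor value. At low levels the arms run among the other features, whose changes past the threshold are mostly under 1, and 142 of the 247 circles lie beyond 1.

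Among the 33581 features with no floor value on any array, 1641 were past the threshold, 985 higher and 656 lower in NAC muscle. Their median change was 0.386 on the log2 scale, with a 5th to 95th percentile from 0.25 to 0.74. A change of over 1 was found for 26 of them, 8 higher and 18 lower. On 507 of the 33581 features the groups did not overlap, where chance gives 13.4. Calls were more frequent at higher levels. With these features ranked by mean level and divided into 4 equal parts, 0.453%, 2.0%, 4.46% and 12.6% of these features were past the threshold from the dimmest to the brightest part, and in each part more were higher than lower in NAC muscle (24 against 14, 96 against 72, 231 against 143 and 634 against 427).

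The files do not pair feature numbers with genes, so single features are given by number. Feature 18051, ranked as the largest rise by the fixed rule, was listed at the floor on all 9 untreated arrays and had an intensity of 1928 ± 144 (SD, n = 6) in NAC muscle. Feature 27039, ranked as the largest fall, had an intensity of 4398 ± 796 (SD, n = 9) in untreated muscle and was listed at the floor on all 6 NAC arrays. Both ranks rest on the floor value, and no p is given because 1 group is a constant without spread. Both features are among the 15 with a median intensity of over 1000 where read, for which a differing array layout is a hypothesis, given in the last part. Of the 10 largest rises 9, and of the 10 largest falls 10, had the floor value on every array of 1 group. Past the threshold, 80 features changed by over 2 on the log2 scale, and 79 of them held a floor value. Chosen after the values were seen, feature 30511 had the largest rise among features with no floor value, from 10.7 ± 3.6 (SD, n = 9) to 114 ± 19.3 (SD, n = 6). It alone of these 80 held no floor value. On the untreated arrays its intensities, from 6.45 to 16.9, were all below the array median of 18.28. Whether feature 30511 shares the source of the floor pattern was not tested. Its log2 change was 2.29 ± 0.102 (SE), with a 95% interval from 2.07 to 2.5 and a limma adjusted p of 1.29e-12, which is 4.88-fold on the log2(value + 16) scale, and 6 of 6 NAC arrays lay above every untreated array. The size depends on how low intensities are treated: the log2 change was 3.35 with a constant of 1 and 1.82 with intensities under 32 set to 32. Chosen in the same way, feature 16925 had the largest fall, from 236.7 ± 169 (SD, n = 9) to 65.5 ± 82.8 (SD, n = 6). Its log2 change was -1.86 ± 0.446 (SE), with a 95% interval from -2.79 to -0.927 and a limma adjusted p of 0.0182, and 5 of 6 NAC arrays lay below every untreated array. The call of feature 16925 was lost without NAC replicate 5 (log2 change -1.64), without NAC replicate 6 (-1.60) and under 3 other settings, while feature 30511 kept its call in all 29 settings run.

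**Figure D4:**
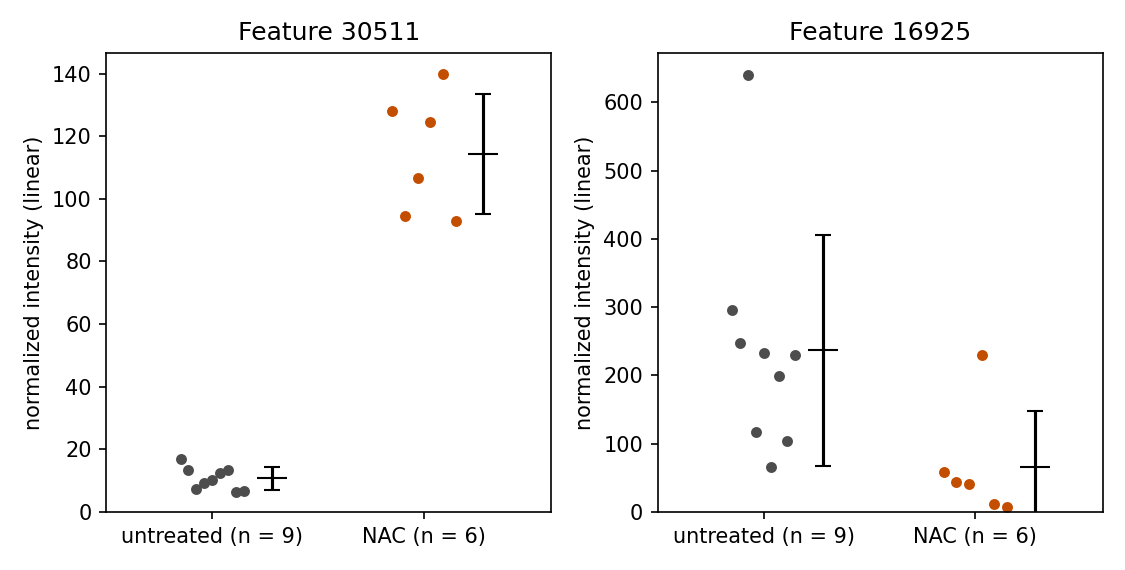
Normalized intensity (y axis, linear) of feature 30511 (left) and feature 16925 (right), 1 point per mouse, with the mean and SD of each group drawn beside the points. All 6 NAC values of feature 30511 lie above the 9 untreated values, whereas for feature 16925 1 NAC mouse lies among the untreated mice; the lower end of its NAC bar falls below 0 and is not drawn.

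The labels also allow a look at the duration of treatment, from 30 to 35 weeks over the 6 NAC mice. The durations rise by 1 week in the order in which the samples are listed, and whether each was recorded for its own mouse is not given in the sources used here. No feature had a slope per week past the threshold (limma, 0 of 36227), and the smallest adjusted p was 0.968 (limma). An unadjusted p under 0.05 was found for 1711 features, or 4.72%. In the simulation, in which 200 features changed at once, slopes of 0.4 per week on the log2 scale were mostly found (90.9%). Slopes of 0.2 were found in 25.4% of cases and slopes of 0.1 in 0%. Over the labelled weeks a slope of 0.4 adds up to far more than 0.404, the median group difference among the 1908 features. Trends of the size of most group differences could thus have been missed. The Benjamini-Hochberg adjustment is stricter when fewer features change, so a lone slope of 0.4 could have been missed.

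The last comparison asked whether mice of 1 group varied more than mice of the other, and no difference in spread was detected. The median SD within a group over features was 0.163 on the log2 scale in NAC muscle and 0.167 in untreated muscle, a ratio of 0.973, and a two-sided permutation test over all 5005 splits gave p = 0.67. The test is approximate, since each group's mean was removed first.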

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

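The tests on untreated replicate 7 in this part were chosen after its values had been seen, whereas the rule for a sample that stands apart was set before the data were examined. That rule compared the gap between the highest or lowest array of a group and its nearest neighbour with the range of the group. It was applied to 16 groups of values, of which 5 met it. Chance gives about 1 in 20 for independent, normally distributed values. Untreated replicate 7 and NAC replicate 5 each met the rule on more than 1 measure, so the 5 are not independent.

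Untreated replicate 9 had 401 features at the floor value, against 322 on the untreated array with the next highest number. NAC replicate 5 had the lowest mean correlation with its own group, 0.9758 against 0.9797 for the next lowest, and a second principal component of 15.65 against -3.06 for the next highest NAC array. Untreated replicate 7 had a first principal component of -33.55, further from the NAC arrays than any other untreated array (-21.68 for the nearest). Without features with a floor value it was at -40.5, against -15.1 for the nearest. Its mean correlation with the NAC arrays was 0.9557, against 0.9642 for the next lowest untreated array.

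Untreated replicate 7 was followed up through features with no floor value that lay over 0.5 log2 units outside the range of all other arrays, a gap chosen after a wider one had been looked at. It had 349 such features above all other arrays and 21 below, 370 in all, while the next highest total was 160, on untreated replicate 9. Unread spots filled in with the floor value cannot account for these 370 features, since they were chosen to hold none. For the place of replicate 7 on the first component, the tables argue against unread spots. Its 289 floor values lay within the 246 to 401 of the other untreated arrays, and it stayed apart without floor features (-40.5, against -15.1). A local defect stays open: 10.5% of the 370 features had another one within 5 numbers, against a median of 9.73% and a highest value of 18.4% over 1000 random sets. With replicate 7 left out of the comparison, its 349 high features had a median NAC minus untreated change of -0.283, below all of 1000 random sets matched on level (lowest -0.032), and 332 of them were lower in NAC muscle. The random sets were not chosen for being high on 1 array, so they cannot decide whether replicate 7 lies further along the axis that separates the groups. The place of replicate 7 on the first component and its low correlation with NAC arrays, both seen beforehand, also make such a low median likely in advance. Among features that were highest on other untreated arrays, 37 of 41 for replicate 1, 53 of 73 for replicate 3 and 21 of 28 for replicate 8 were lower in NAC muscle, but 15 of 39 for replicate 9, with no random sets drawn. The rest had few such features: 5 of 8 (replicate 2), 5 of 10 (replicate 4), 5 of 5 (replicate 5) and 4 of 6 (replicate 6). Median changes also lay below -0.032 on these arrays, such as -0.238 for replicate 6, except for replicates 4 (0.00138) and 9 (0.0519). The labels give nothing that sets replicate 7 apart, and no biological explanation was tested.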

How the results depend on the processing

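Tests added after the data were seen are those on floor values, which include the arrays' correlations and principal components, on the trend along the feature number and on untreated replicate 7 left out together with the floor features. Quantile normalization and median centring moved nothing, since the deposited arrays already shared 1 distribution, and so say nothing about stability. The 1908 features past the threshold became 959 with intensities under 32 set to 32, a setting that flattens dim features, and 3024 at an adjusted p under 0.10. Leaving out 1 array gave 1252 (without NAC replicate 3) to 2034 (without untreated replicate 1), and leaving out untreated replicate 7 with the floor features gave 1264. The other settings lay between 1509 (floor values missing) and 2147 (the 50% of features with the higher level, 18114 tested). The features were not all the same. Of the 1908, 892 passed with intensities under 32 set to 32 and 1541 with the higher 50%. Without NAC replicate 3 it was 1206 of the 1908, and without untreated replicate 1 it was 1732. In all 29 settings more features were higher than lower in NAC muscle, from 55% to 66.6% of calls. Feature 16925 lost its call in 5 settings, and feature 30511 in none. The number lower in NAC muscle, 785, fell to 320 with intensities under 32 set to 32 and ranged from 485 (without NAC replicate 3) to 915 (without untreated replicate 1) with 1 array left out. The count of features without overlap fell to 497 with intensities under 32 set to 32. The duration trend gave 0 calls in all 9 alternatives, and no alternative moved the spread ratio past its threshold. The spread ratio moved most, to 0.848, with the 50% of features with the higher level (two-sided permutation test, p = 0.14). Not run, for lack of gene names, were the gene list tests with their alternatives, covariates from control and sex-linked genes, filters on probe set names and 1 probe set per gene. No paired analysis was possible because the labels give the groups no shared replicate numbers. Background is unknown here, and level sets a limit: 0.453% of the dimmest and 12.6% of the brightest of 4 equal parts of the features without a floor value passed.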

Other observations

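In this part only the splits of the arrays were planned, and the other tests were chosen after the results had been seen. As the files pair no feature with a gene, no further gene groups or cell types are described.

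The 247 features with the floor value on every array of 1 group and on no array of the other are hard to ascribe to transcripts that were silent in that group. Silent transcripts listed at the floor would put many features at the floor on all 15 arrays, and 1 feature was. A candidate explanation is spots that could not be read on the arrays used for 1 group and were filled in with the floor value, which would strike features whatever their level: the median percentile of their level in the group that read them was 53.2, within the 43.89 to 56.22 of the central 95% of 10000 random sets. A further candidate is an array layout whose control spots differed between the groups. Of these features, 15 had a median intensity of over 1000 where read, 6 on untreated and 9 on NAC arrays, and 33 of their 51 within-group pairs lay within 150 of a whole multiple of 3625 in feature number, while random sets, each at its own best step between 3000 and 12000, gave a median of 9 and at most 21 over 1000 sets. The regular spacing had been noticed before this test, and the tolerance and the brightness limit were set after it, so it remains a hypothesis; with tolerances of 75 and 300, each with its own best step (3625 and 3600), the pairs numbered 31 and 33, against at most 16 and 28.

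The count of 1908 features past the threshold was set against chance, floor features, a trend along the feature number and a batch. Of 100 splits of the 15 arrays into 6 and 9, drawn from 5005 possible ones, 1, the real one, gave as many features. The highest of the others gave 12. The other splits mixed NAC and untreated arrays, so the difference between groups could widen the spread within their parts and lower their counts. All 247 floor features passed under the real grouping, which alone put its count above 12. The splits therefore say little about the other features. The real grouping was extreme among those drawn, which makes chance an unlikely source of the total but does not exclude it. Features with a floor value were not the main source of the 1908, since 1581 of the 1908 passed when all of them were left out. Neither was a trend along the feature number, since 1969 features passed after its removal, 1705 of them among the 1908. Uneven hybridisation over the array stays untested, since the sources used here do not say whether feature numbers follow position. An array lot or processing batch that followed the treatment stays open and cannot be told apart from NAC. Of 259 features at the floor on 5 to 10 arrays, 247 parted the arrays exactly by group. By this definition, the sets of arrays that the 247 define cannot hold both groups, so the difference could not be looked for within a batch. How far a technical difference also shaped the 1641 calls with no floor value was not tested. The effect of NAC itself also stays among the open explanations, and telling it from a batch would take arrays of both groups from 1 lot.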
